A study of Homo sapiens with 12 samples.

How the data were processed

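RNA immunoprecipitation sequencing was analysed from 12 libraries of U373-MG cells, 4 each of ADAR3 IP, pre-immune IP and input, grouped and numbered from their titles. Per the labels' protocols, ribosomal RNA was depleted, libraries were made with a strand-specific kit and amplified for 15 cycles, and input libraries started from 1 µg of total RNA while each IP library used all the RNA recovered. The molecule label reads polyA RNA, which differs from that protocol and was left open. STAR 2.7.7a, featureCounts, DESeq2 and the build GRCh38 are named in the submitters' processing notes, without their roles. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical copies are uncertain.

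The authors deposited 1 table for the 8 IP libraries (28556 genes) and 1 for the 4 input libraries (28061 genes). The deposited values are a normalized signal, gene counts divided by a size factor per library. This was tested on the values: 100% of them were whole multiples of the value of 1 read, at a tolerance of 0.001 reads, so whole reads and depths were recovered. Median-ratio size factors recomputed within each table differed from the deposited ones by at most 0.013% and 0.0068%, so the tables were normalized separately. The IP table also holds the authors' deposited log2 fold changes of ADAR3 IP over pre-immune IP. It holds the authors' p-values as well, with an adjusted p for 17946 genes. No column of other samples was present. Both tables leave out genes at 0 in all their libraries.

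The files name genes by Ensembl ID and do not pair them with symbols. The reference table of 59792 genes held 0 Ensembl IDs, so 0 of 31707 IDs could be named. The 26 gene lists fixed before the data were examined, the genes to be named in every case and the shares per RNA class other than the 10 most abundant genes were therefore not analysed here. The rule for named genes took the largest log2 fold changes in each direction among genes with an adjusted p under 0.05, a mean of at least 20 reads over the 8 IP libraries and full separation of the groups. It was applied to IDs and limited to 2 per direction.

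The planned main test was edgeR on raw counts, or limma on log2(value + 1) if the files held normalized values, and so limma 3.58.1 (R 4.3.3) was used on the deposited IP values, with a variance trend and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, where the pseudocount understates the change of low genes and a few values at or near 0 can make the difference of mean logs larger than the ratio of means. The comparisons with input, the set of genes above both controls and a fit of all 12 libraries were planned only for deposited raw counts and were not run, although the recovered reads would allow such fits.

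The minimum level for a gene to be tested was not fixed beforehand and was chosen after seeing the data. A mean normalized count of at least 10 over the 8 IP libraries was fitted first and called 659 genes higher and 244 lower. It failed when tested on simulated data: with real means, depths and the spread of each group and no gene changed, limma called 513 of 14605 simulated genes higher and 8 lower. On the same simulated data edgeR made 0 false calls among 13764 genes, and limma with variance weights per group 0 among 14605. In 5 further simulated sets without change at this minimum, added after the data were seen, limma made 403 to 553 false higher calls and 1 to 6 lower. edgeR made 0 higher and 0 to 1 lower in those sets, and the group weights 0. In 5 more sets without change, also added later, edgeR with its own filter made 0 false calls. With 200 genes changed and its own filter, edgeR made 415 false higher calls and 13 lower in the first simulated set, and 0 to 2 higher and 0 to 3 lower in each of 20 sets added later. The reason for the first outcome was not tested. limma was kept because the plan named it for normalized values. Minimums of 10, 50, 100, 200 and 400 were then compared on simulated data while their counts on the real data were also in view, as were robust limma, variance weights per group and edgeR. The rule adopted was the lowest minimum with no false call by limma when no gene changed, which is 50. A minimum of 100 was for a time used as the main setting after its real counts, 278 and 222, had been seen, and was withdrawn in favour of that rule. Counts at all 5 minimums are given in the closing section.

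At a minimum of 50, limma made 0 false calls among 11024 simulated genes of the comparison of ADAR3 IP with pre-immune IP when none was changed, and 0 in each of 5 further sets. With 200 genes changed it made 1 false call among 10995 genes. It recovered 18 of 50 genes raised 4-fold and 12 of 50 lowered 4-fold, but 3 of 50 raised and 4 of 50 lowered 2-fold. Most changes of 2-fold would therefore be missed. The median log2 fold change over all simulated genes was 0.33 with no gene changed, so a positive median arises on this scale with no changed gene. With edgeR, which scales libraries in its own way, the median on the same simulated counts was -0.097. The simulated groups differed only in depth and spread, so the positive median came from these on the log2(value + 1) scale. The parts of depth and spread were not tested separately.

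Alternatives covered library size alone, TMM factors, pseudocount 0.1, other filters, robust variances, no variance trend, library and group weights, the replicate number as a block, thinning to equal depth, each library left out, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. DESeq2 gave the same counts, 1571 and 1010, as the authors' adjusted p. Single measures per library were compared with exact permutation tests over 70 assignments, two-sided. Chi-square tests of counts between replicates gave 2.53 to 52.8 per degree of freedom, so no pair looked like a single library deposited under both names. The labels give no batch, and depth separates the ADAR3 and pre-immune groups fully. Reads without molecular identifiers are not independent molecules. Intervals on pooled reads treat them as independent, so they cover the counting error of reads only and may be too narrow for molecules. Python 3.11.15 with scipy 1.17.1 was used for these steps.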

Results

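RNA bound to endogenous ADAR3 was measured in U373-MG cells, a human glioblastoma line. ADAR3 is a double-stranded RNA-binding protein of the adenosine deaminase family for which no editing activity is known. The cells were crosslinked with ultraviolet light and sonicated, and RNA was recovered by immunoprecipitation (IP). The 12 libraries fall into 3 groups of 4: IP with an antibody to ADAR3, IP with pre-immune serum as the control for non-specific recovery, and input RNA taken before IP. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

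The groups differed in depth and in the diversity of the RNA they held. ADAR3 IP libraries held 23999234 to 30156884 reads assigned to genes, pre-immune libraries 1875461 to 4946149 and input libraries 4873428 to 12772412. After every library was thinned to 1875461 reads, 17314 ± 453 genes (SD, n = 4) had a read in ADAR3 IP, 12740 ± 787 in pre-immune IP and 17780 ± 90.8 in input. The number was higher in every ADAR3 IP library than in every pre-immune library (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 can give; Benjamini-Hochberg adjusted p = 0.0334 over 7 comparisons). ADAR3 IP and input did not differ past the threshold in this count (exact permutation p = 0.1143, adjusted p = 0.1143).

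The 10 most abundant genes of each library took 11.8% ± 0.667 of reads in ADAR3 IP (SD, n = 4), 20.5% ± 3.56 in pre-immune IP and 9.66% ± 0.535 in input. All 3 pairs of groups were fully separated (exact permutation p = 0.0286 for each, adjusted p = 0.0334). Across 17147 genes, which are not independent replicates, read counts at equal depth correlated with the input mean at a Spearman rho of 0.938 ± 0.00468 (SD over 4 libraries) in ADAR3 IP and 0.852 ± 0.0328 in pre-immune IP. Each pre-immune library correlated less well with input than each ADAR3 IP library (exact permutation p = 0.0286, adjusted p = 0.0334). Replicates also spread unequally. The median SD between replicates on the log2 scale was 0.19 in ADAR3 IP, 0.69 in pre-immune IP and 0.098 in input, among genes with a mean normalized count of at least 100.

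**Figure D1:**
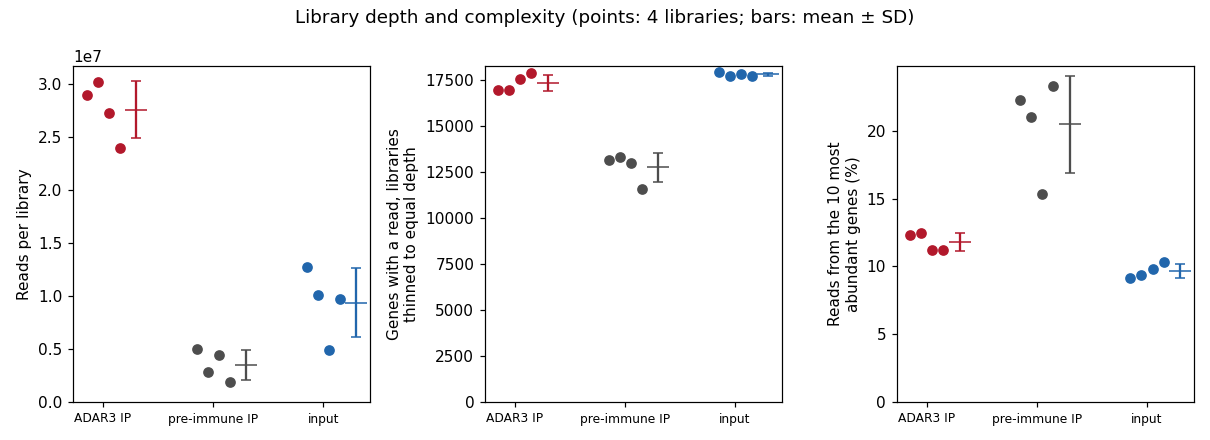
Reads per library, genes with at least 1 read after thinning to equal depth, and percent of reads from the 10 most abundant genes, for the 4 libraries of each group (points) with mean and SD (bars). The pre-immune libraries sit between 1875461 and 4946149 reads, below all 4 ADAR3 IP libraries, and have fewer genes and a larger top-10 share.

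The comparison of ADAR3 IP with pre-immune IP asks which RNAs made up more of the antibody IP than of the serum IP. Each IP library used all the RNA recovered and was scaled by a size factor, so amounts of RNA recovered are not compared. A gene lower in ADAR3 IP may still have been recovered in a larger amount there. Of 11112 genes tested, 259 were higher and 193 lower in ADAR3 IP (limma on log2(normalized count + 1), Benjamini-Hochberg adjusted p under 0.05). The 259 higher genes had a median log2 fold change of 1.04, with quartiles of 0.79 and 1.37, and the 193 lower genes a median of -1.14, with quartiles of -1.48 and -0.89. These values stand against a median of 0.25 over all tested genes. A change of at least 4-fold was seen for 30 of the higher and 23 of the lower genes, but also for 1182 of the 10660 genes that were not called, so size alone did not set the called genes apart. The 4 ADAR3 IP libraries lay entirely above or below the 4 pre-immune libraries for all 259 higher genes and 192 of the 193 lower ones. The same full separation held for 15.5% of all tested genes. Chance gives 2.86% only where the libraries of both groups are interchangeable. Here the groups spread unequally (median SD of 0.19 in ADAR3 IP and 0.69 in pre-immune IP), so that figure is no fair baseline. How often full separation arises with no changed gene was not tested. The called genes were chosen on these same libraries, so their separation adds no support.

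Among higher genes, those with the largest fitted change by the rule set beforehand were ENSG00000188064 and ENSG00000245614. Normalized counts of ENSG00000188064 were 180 ± 47.0 in ADAR3 IP and 1.34 ± 1.67 in pre-immune IP (SD, n = 4 each). It had only 2 reads over the 4 pre-immune libraries against 2204 in ADAR3 IP. The ratio of pooled reads, each divided by its group's total, was 140, with a 95% exact interval of 38.7 to 1156. That interval covers the counting error of reads alone, taken as independent, and may be too narrow. Its log2 fold change was 6.53 ± 1.51 (SE; limma adjusted p = 0.0363). For ENSG00000245614, normalized counts were 206 ± 18.3 in ADAR3 IP and 4.46 ± 6.62 in pre-immune IP, and the log2 fold change was 6.15 ± 1.46 (SE; limma adjusted p = 0.0407). Its ratio of pooled reads was 36.3, with an interval of 19.1 to 79.5, so the fitted value lies above that ratio. Input held 11.95 CPM (reads scaled to library totals) of the first and 8.32 CPM of the second. ADAR3 IP held 20.25 and 23.2 CPM of them, and pre-immune IP 0.14 and 0.4996 CPM, from only 2 and 9 reads. Their large positive fold changes thus reflect mostly pre-immune levels far below input, with ADAR3 IP above input to a smaller extent.

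Among lower genes, ENSG00000143632 had 2.54 ± 2.82 normalized counts in ADAR3 IP and 305 ± 162 in pre-immune IP (SD, n = 4 each). Its log2 fold change was -6.70 ± 1.37 (SE; limma adjusted p = 0.0213). ENSG00000169855 had 0.970 ± 0.255 normalized counts in ADAR3 IP and 150 ± 40.6 in pre-immune IP, with a log2 fold change of -6.23 ± 1.499 (SE; limma adjusted p = 0.0433). Both were scarce in input, at 0.219 and 0.151 CPM, and in ADAR3 IP, at 0.288 and 0.109 CPM. Pre-immune IP held 32.0 and 16.1 CPM of them. Their negative fold changes thus reflect pre-immune levels far above input, with ADAR3 IP close to input. Over 4 libraries, the first had 423 reads in pre-immune IP against 32 in ADAR3 IP, and the second 218 against 12. The ratios of pooled reads, pre-immune IP over ADAR3 IP, were 104 and 143. All 4 genes passed narrowly with limma: at a pseudocount of 0.1 their adjusted p ranged from 0.0604 to 0.108, and over all alternatives, DESeq2 included, from 5.149e-36 to 0.285. In the authors' deposited table, the log2 fold changes of the 4 genes in this order were 7.01, 5.15, -6.91 and -7.27.

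**Figure D2:**
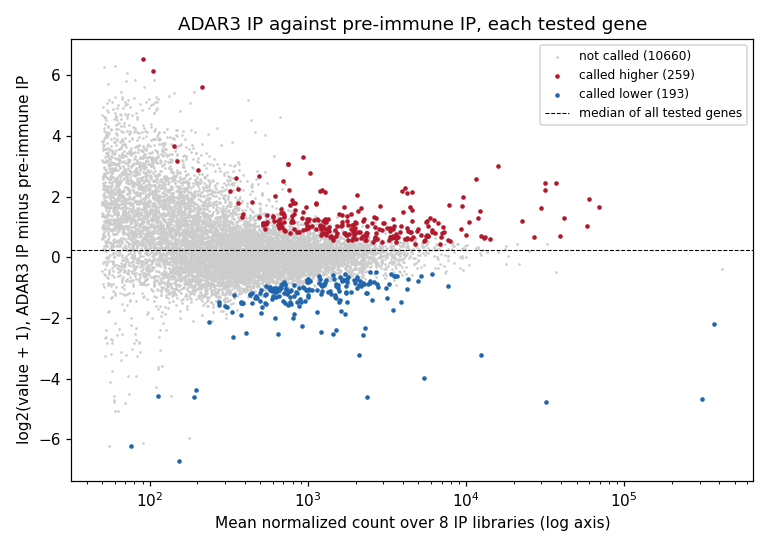
Difference in log2(normalized count + 1), ADAR3 IP minus pre-immune IP, against the mean normalized count over 8 libraries (log axis), 1 point per tested gene. Called genes are coloured (259 higher, 193 lower), and the dashed line marks the median of all tested genes, 0.25.

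The number of called genes depended on the libraries and on the test. Leaving out ADAR3 IP replicate 1, 2, 3 or 4 left 115, 106, 107 and 121 higher genes and 72, 65, 68 and 90 lower ones. Leaving out pre-immune replicate 1, 2, 3 or 4 instead gave 315, 314, 355 and 446 higher and 229, 207, 244 and 345 lower. Pre-immune replicate 4 is the shallowest library, but the counts rose whichever pre-immune library was left out. limma fits 1 variance per gene over both groups, which spread unequally. The cause of this pattern was not tested. In the authors' deposited table, 1571 genes were higher and 1010 lower at an adjusted p under 0.05, including all 259 and all 193 called here, and 0 genes were called in opposite directions. edgeR's quasi-likelihood test on the recovered reads of 11104 of these genes called 299 higher and 194 lower, of which 255 and 168 were shared, and with its own filter, which admitted 14470 genes, 998 higher and 244 lower. Other scalings moved the split between directions, from 57.3% higher to 69.4% with library size alone and 77.7% with TMM factors, which moved the median of all tested genes from 0.25 to 0.33 and 0.39.

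Levels in the IPs were set beside input in CPM from recovered reads. The IP and input tables were normalized separately, and tests against input had been planned only for deposited raw counts, so these differences were not tested. The called genes had been chosen on the same IP libraries. The 259 higher genes had a median log2 ratio of ADAR3 IP over input of 0.98 and of pre-immune IP over input of -0.16. For 229 of them every ADAR3 IP library exceeded every input library, compared with 3251 of all 11112 tested genes. Every pre-immune library lay below every input library for 92 of the 259, compared with 1816 of all tested genes. Both held for 62 of the 259 and for 138 of all tested genes. The 193 lower genes had medians of -1.44 in ADAR3 IP and -0.47 in pre-immune IP relative to input. For 166 of them every ADAR3 IP library lay below every input library, compared with 3520 of all tested genes. For 101 of the 193 every pre-immune library also lay below every input library. Genes tested and not called had medians near 0, at -0.0049 for ADAR3 IP and -0.041 for pre-immune IP.

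The higher genes took 17.8% ± 0.581 of reads in ADAR3 IP (SD, n = 4), 7.32% ± 0.501 in pre-immune IP and 13.8% ± 0.372 in input. The lower genes took 3.63% ± 0.199, 17.4% ± 3.13 and 8.38% ± 0.635 of reads in the same order. A few members carried the pre-immune share: 10 of the 193 lower genes, which were far scarcer in input than in both IPs, took 13.6% ± 3.25 of pre-immune reads. The other 183 took 1.85% ± 0.134 of reads in ADAR3 IP, 3.81% ± 0.248 in pre-immune IP and 8.37% ± 0.638 in input. Called genes were more abundant than the typical tested gene, which detection power alone could produce. In simulated data at a minimum of 400, limma recovered 46 of 50 genes raised 4-fold and 42 of 50 lowered 4-fold. At a minimum of 50 it recovered 18 and 12. The median higher gene stood at 275 CPM in ADAR3 IP, 137 CPM in pre-immune IP and 151 CPM in input, and the median lower gene at 69.6, 149 and 197 CPM, against 36.3, 36.9 and 40.5 CPM over all tested genes.

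**Figure D3:**
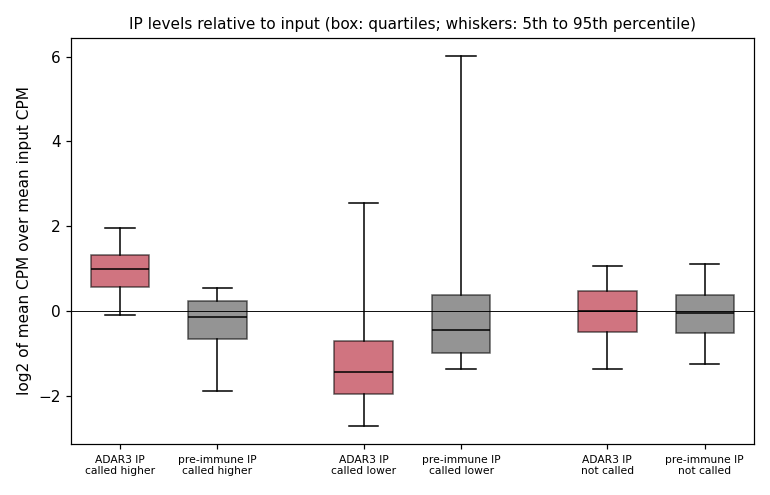
Log2 of mean CPM in ADAR3 IP or pre-immune IP over mean CPM in input, for genes called higher, called lower or not called between the IPs (boxes are quartiles, whiskers the 5th to 95th percentile, with 0.1 CPM added to each mean). Higher genes have a median of 0.98 in ADAR3 IP and lower genes a median of -1.44.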

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

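No library stood apart from the other 3 of its group in any of the 28 sets of 4 values examined, by Dixon's test at its 95% critical value. The sets covered depth, genes with a read at equal depth, shares of the most abundant genes, correlation with input, genes with reads in 1 library alone, single-read shares and the normalized counts of the 4 named genes. Chance alone would mark about 1 set in 20.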

How the results depend on the processing

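Settings named first were planned, except where said to be chosen after seeing the data. The main counts of 259 higher and 193 lower genes kept both directions in every setting, with no called gene reversed. The count of higher genes became 1493 without a filter on low values, 739 at a mean CPM of at least 1, 1571 with DESeq2 and 142 with an absolute log2 fold change of at least 1. Lower genes became 1010 with DESeq2 and 125 with that fold change. In 5 simulated sets without change, limma made 653 to 753 false higher calls without a filter and 491 to 601 at that CPM, while edgeR with its own filter made 0. Of settings chosen after seeing the data, a minimum mean normalized count of 10 gave 659 higher and 244 lower, 100 gave 278 and 222, 200 gave 314 and 250, and 400 gave 383 and 264. edgeR on recovered reads gave 998 and 244, TMM factors 449 and 129, no variance trend 74 and 78, library weights 283 and 113, group variance weights 344 and 164, and equal depth 222 and 165. The cause of these shifts was not tested.

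Leaving out 1 library gave 106 (without ADAR3 IP replicate 2) to 446 (without pre-immune IP replicate 4) higher genes and 65 to 345 lower ones, from the same libraries. The remaining 3 ADAR3 IP libraries gave at most 121 higher and 90 lower. The difference in top-10 share, 8.69 percentage points, ranged from 7.75 to 10.4, and that in genes with a read at equal depth, 4574 (chosen after seeing the data), from 4188 to 4766. Each then had an exact permutation p of 0.0571, the smallest that 4 against 3 can give.

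With the replicate number as a block, limma called 263 higher and 140 lower genes, 211 and 131 of them shared with the main counts, and edgeR with the block, chosen after seeing the data, 395 and 127. Deviations of same-numbered libraries correlated at -0.0022 to 0.0254, all under 0.1, so the numbers are not taken to pair libraries. The wide spread between pre-immune replicates (median SD of 0.69) could hide a shared effect, so low correlations do not exclude pairing. With the block in limma none of the 4 named genes passed (adjusted p from 0.0765 to 0.182); with the block in edgeR all 4 did (0.00547 to 0.0329). The 4 named genes kept their direction in all 98 pairs of gene and setting run and passed the threshold in 69. Gene list alternatives and those for comparisons with input were not run. Depth limits low genes most, since the shallowest pre-immune library held 1875461 reads.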

Other observations

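The tests below of shallow sequencing, of calls at equal depth and of an outside source of RNA and the rule that picks the 14 genes were chosen only after the results were seen. A small set of RNAs was far more abundant in both IPs than in input. With a geometric mean of at least 5 CPM over the IPs and an input level under 1/20 of it, 14 genes were found. This rule does not require each IP by itself to lie far above input for each gene. They took 18.6% ± 3.73 of reads in pre-immune IP (SD, n = 4), 5.86% ± 0.417 in ADAR3 IP and 0.0150% ± 0.00485 in input. The most abundant of them in input stood at 120 CPM there and made up 80.3% of the set's input share. Of the 14, 10 were among the genes called lower in ADAR3 IP and 0 among those called higher, and their log2 fold changes ranged from -5.95 to -0.37. An input limit of 1/10 or 1/50 gave 16 or 12 genes.

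A candidate explanation for these 14 genes is one outside source of RNA mixed into each IP. A single source would hold its RNAs at fixed proportions, so their fold changes between the IPs would be alike. For 7 of the 14 the 95% limma interval left out their median of -3.59, which argues against a single source of fixed makeup. Several sources, or RNA recovered by serum or beads to different extents, stay open and were not tested. No biological explanation was tested.

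Of the 35 splits of the 8 IP libraries into 4 and 4, only the real one, 1 split, gave as many called genes. It gave 452, against a highest of 0 in the other splits. Every other split mixes ADAR3 IP with pre-immune libraries, which widens the spread within each side, so few calls there were nearly fixed. The outcome shows that the groups of libraries differ and does not tell how many calls are due to chance. Depth differed fully between the groups, and with every IP library thinned to equal depth 222 genes were called higher and 165 lower. Of the 259 higher genes 217, or 83.8%, were still called, and 157 of the 193 lower genes, so those calls did not need unequal depth. Thinning keeps proportions and mostly cuts the deep ADAR3 IP libraries, so many calls were likely to persist, and the result shows no more than that. For the calls lost at equal depth, where thinning also costs power, depth stays open as a cause. That 100% of the higher genes kept at least 0.5 of their log2 fold change decides nothing, since thinning keeps proportions and the outcome was nearly fixed. Thinning does not remove the lower diversity of the pre-immune libraries, which stays open as a contributor, as does binding to ADAR3, which was not tested apart from other differences in recovery between antibody and serum.

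Many genes had at least 20 reads in 1 library and 0 in its 3 replicates: 60 to 159 genes per ADAR3 IP library, 233 to 542 per pre-immune library and 0 in each input library. Every ADAR3 IP library, with at least 60, was deeper than every input library. Greater depth also lets more genes reach 20 reads, so the contrast with input cannot decide on shallow sequencing as the cause there. The ADAR3 IP libraries themselves had similar depths, 23999234 to 30156884 reads. Reads sampled from the same RNA mixture would then hardly number at least 20 in 1 library and 0 in its 3 replicates. For these genes of the ADAR3 IP libraries, that argues against shallow sequencing alone. For the pre-immune libraries, the 4 input or the 4 ADAR3 IP libraries were thinned together to the 4 pre-immune depths, in 18 and 24 orders. An input library then held 0 such genes and an ADAR3 IP library at most 1, against at least 233 in a pre-immune library, which argues against depth alone. A gene seen in 1 thinned input library only had at most 8 reads there. If few RNA molecules had been amplified many times, scarce genes would show few single reads. Among genes at 0.1 to 1 CPM in input that were seen at equal depth, the share with exactly 1 read was at most 28.4% in a pre-immune library and at least 63.6% in an input library, a test fixed before its result was seen. Few RNA molecules amplified many times in the pre-immune IP would give so low a share. However, the genes were picked by their low level in input, which keeps most of them at single reads there. Genes recovered more in an IP than in input would also show more than 1 read, so this contrast does not decide the cause. ADAR3 IP libraries lay between, at 38.2% to 43.6%. No biological explanation was tested.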
